A study of Homo sapiens with 6 samples.

How the data were processed

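RNA of MDA-MB-468 cells given DMSO or CS-6 was measured in 6 libraries, 3 per group, and groups were taken from the labels. Per the labels, RNA was extracted with Trizol, and total RNA is named as the molecule measured with Illumina library protocols. The deposited count table holds whole numbers of reads per Ensembl gene as the authors made them, with no normalization, for 57992 genes, of which 26333 were at 0 in every library. The aligner, the counting tool, the annotation and the strandedness are not given in the sources used here. The submitters' processing notes name the genome build GRCh38. The FPKM values deposited by the authors are counts divided by gene model length and by the library total, checked on the files, where count and FPKM gave 1 length per gene for 100% of genes (relative spread under 1e-9). The log2 fold changes deposited by the authors compare CS-6 with DMSO and come from DESeq2 per the submitters' processing notes, version not given. The adjusted p-values in that deposited table belong to the authors' DESeq2 comparison, and genes it marks as significant have an adjusted p under 0.01 and an absolute log2 fold change of at least 2, as tested on the values.

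Choices of tests, filters, gene lists and alternatives were made before the data were examined, except where the closing section says otherwise. Genes were filtered with filterByExpr of edgeR (minimum count 10, minimum total count 15), which left 15684 genes. Counts were scaled with TMM factors and tested with the edgeR quasi-likelihood test (glmQLFit, glmQLFTest), two-sided, with no covariate, and p-values were adjusted by Benjamini-Hochberg with an FDR threshold of 0.05. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used, and tables and figures were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The common dispersion was 0.00116, a biological coefficient of variation of 3.41%. CPM values are counts scaled to the library size after TMM factors. The SE of a log2 fold change is its absolute value divided by the square root of the edgeR test's F statistic. It can understate the error of genes with few counts in a group. Positions are GRCh38, from the deposited annotation. Current symbols were found for 31225 genes by Ensembl identifier.

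A floor of 3 counts corresponds to 0.158 to 0.167 CPM in the DMSO libraries and 0.212 to 0.223 CPM in the CS-6 libraries, with TMM factors. Genes with 0 counts in a group were compared against 3 counts over that group, and genes with 1 to 3 counts were given a ratio with an exact (Clopper-Pearson) 95% interval. Both cover counting error only, since reads without molecular identifiers are not independent molecules.

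The gene lists numbered 44, with 1237 entries, of which 1185 had a gene with a count, 50 were at 0 in every library and 2 had no match. Each list with at least 5 tested members was tested with camera of limma, two-sided, on log2 CPM (prior count 2) with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 42 lists. It was also tested with an estimated correlation and with fry. Intervals of list medians are 95% intervals from resampling the members 10000 times. They treat members as independent and carry no error between libraries or of the scaling. The adjusted p given beside a list is camera's, and that given beside a gene is edgeR's. GO terms of the deposited annotation with 10 to 500 genes were tested with a one-sided Fisher's exact test against tested genes carrying a term of that kind.

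Named genes were chosen by rule. They are the 10 largest rises and 10 largest falls among changed protein-coding genes with a mean CPM of at least 5, groups that do not overlap and a symbol that is not a clone name, the 4 members with the smallest adjusted p of each called list, up to 2 changed members of each other list, and a panel of 18 genes. A panel gene with a mean CPM under 1 was described as low. Some genes that the rule names are not reported here.

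Alternatives were DESeq2 size factors, upper-quartile factors, total counts only, no low-count filter, a CPM of at least 1 in at least 3 libraries, the DESeq2 Wald test, limma on log2 FPKM with a pseudocount of 1 or 0.1 and a mean FPKM of at least 0.5, leaving out each library in turn, a replicate block, an estimated correlation, fry and a background of protein-coding genes. The tests were run on simulated counts for CS-6 against DMSO with 15684 genes, of which 200 were given a change. The edgeR test recovered 46%, 86%, 94% and 100% of genes with a simulated log2 change of 0.25, 0.5, 1 and 2, and 4.68% of its calls were false. DESeq2 recovered 38%, 76%, 90% and 100% with 1.30% false calls, and limma 44%, 86%, 94% and 100% with 3.57%. Simulated changes were few and as often up as down, whereas 87.4% of tested genes were called in the data. These rates therefore do not carry over to the data, where the scaling shifts directions. No library was left out of the reported values.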

Results

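RNA was sequenced from MDA-MB-468 cells, an established human triple-negative breast cancer line that carries many copies of the EGFR gene. Cells received either DMSO, the solvent control, or CS-6 (gamabufotalin), a bufadienolide steroid of toad venom, at 18 nmol/L for 24 h. Bufadienolides bind the sodium-potassium pump, as cardiac glycosides do. Each group had 3 libraries. Total counts were 15668161 to 16741405 in the DMSO libraries and 15450357 to 16078740 in the CS-6 libraries, and 24435 ± 41.6 genes (SD, n = 3) had a count with DMSO against 22857 ± 65.2 (SD, n = 3) with CS-6. Counts were scaled to library size (CPM, with TMM factors). Spearman correlations of log2 CPM were 0.995 to 0.997 within groups and 0.861 to 0.870 between them. The first principal component held 94.8% of the variance and separated the groups. Libraries of one group still differed by more than sampling noise, with chi-square statistics of 2.04 to 2.79 per degree of freedom over 15748 genes, so all 6 were kept as separate samples. Nothing in the labels says whether replicates were separate cultures, so p-values here measure only the spread between these libraries, which may be technical.

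The single comparison of the design asks how CS-6 changes the transcriptome of these cells. Most of the measured transcriptome changed. With CS-6, immediate early genes, YAP/TEAD targets, STAT3 targets, autophagy and lysosome genes, genes of mitosis and histone transcripts were higher by a list test, and mitochondrially encoded mRNAs, fatty acid synthesis genes, NRF2 targets and interferon-stimulated genes were lower. These calls used a preset correlation between members (adjusted p of 0.348 to 0.429 with an estimated correlation). Of 15684 tested genes, 13711 changed with edgeR's quasi-likelihood test at a Benjamini-Hochberg FDR under 0.05, 6523 of them higher and 7188 lower. A change of at least 2-fold was seen for 3661 higher and 4667 lower genes. In 13710 tested genes (87.4%) the libraries of both groups did not overlap, where chance gives 10%. The balance of directions rests on the scaling. Higher genes made up 47.6% of the changed genes with TMM factors and 36.7% with total counts only (5100 higher, 8788 lower), a scaling that shifted fold changes by a median of -0.38 on the log2 scale, and upper-quartile factors shifted them by -0.33. With limma on log2 CPM 6453 genes were higher and 7132 lower, and after removing trends on GC content and length 7262 were higher and 6297 lower, so which direction held more genes is not settled. Both limma settings were chosen after seeing the data. Counts are relative to the rest of each library, so a change in total RNA per cell is not measured.

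**Figure D1:**
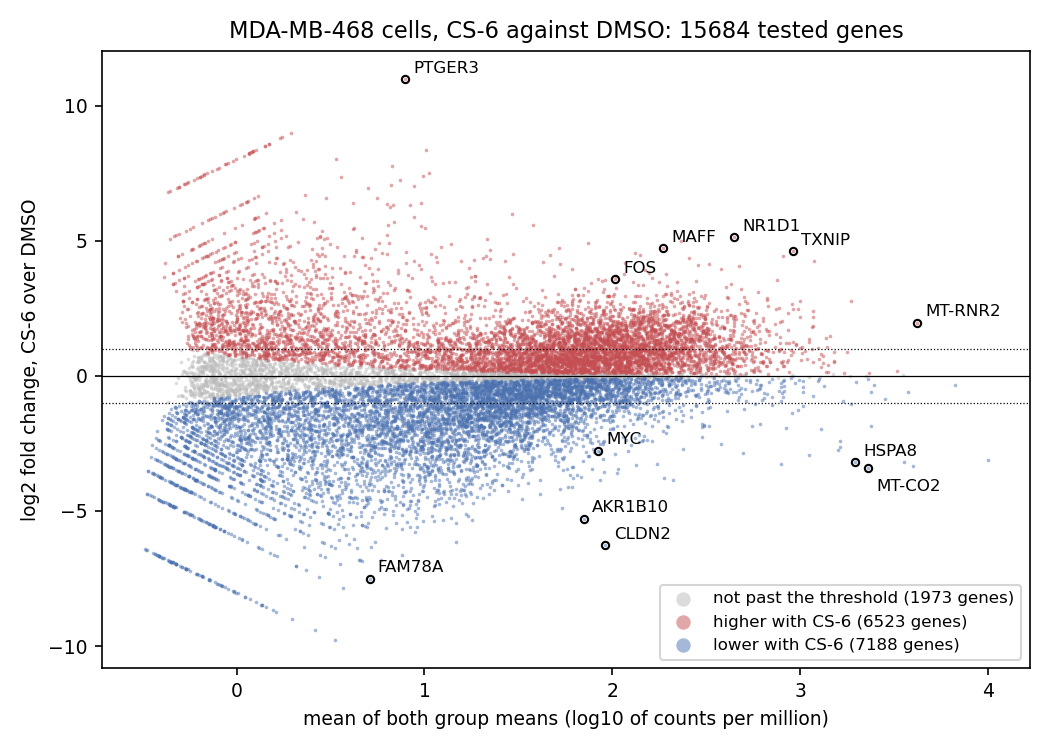
Each point is 1 of the 15684 tested genes, with the log10 of the mean CPM on the x axis and the log2 fold change of CS-6 over DMSO on the y axis. The 6523 genes that rose are red, the 7188 that fell are blue, dotted lines mark 2-fold changes, and the parallel streaks at low CPM are genes with few or 0 counts in a group, whose fitted values depend on a prior count.

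The largest rises among protein-coding genes with a mean CPM of at least 5 were in genes close to silent with DMSO. PTGER3, a prostaglandin E2 receptor (GRCh38 chromosome 1, 70852353 to 71047808, minus strand), had 0 counts in every DMSO library and 15.8 ± 3.83 CPM (SD, n = 3) with CS-6, at least 293-fold higher against a floor of 3 counts over the DMSO group. SEMA4A, a semaphorin, had 3 counts in all DMSO libraries together and 840 with CS-6, a ratio of 375 after scaling (95% counting interval 128 to 1820), and LVRN, an aminopeptidase, had 3 and 556 (ratio 248, interval 84.4 to 1210). Further rises were in the potassium channel subunit KCNS1 (log2 fold change 7.51 ± 0.26 SE), FNDC7 (7.40 ± 0.30), RADIL (7.24 ± 0.28), PKD1L3 (7.08 ± 0.31), the sodium-calcium exchanger SLC8A2 (7.04 ± 0.24), the sialyltransferase ST8SIA5 (6.59 ± 0.29) and the retinol dehydrogenase RDH12 (6.36 ± 0.29). Their DMSO means were 0.090 to 0.141 CPM. With so few counts the SE, derived from the test statistic, can be too small. DESeq2 gave an SE of 0.611 for KCNS1 and 0.667 for RADIL.

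The largest falls took expressed genes to a trace. CLDN2, a tight junction protein of cation-leaky epithelia (chromosome X, 106900164 to 106930861, plus strand), went from 181.1 ± 5.26 to 2.35 ± 0.43 CPM (SD, n = 3), a 76.7-fold fall. FAM78A (chromosome 9, 131258076 to 131276547, minus strand) had 565 counts over the DMSO libraries and 2 over the CS-6 libraries, a ratio of 211 (95% counting interval 58.2 to 1750). The mitochondrial cardiolipin enzyme TAMM41 (-6.80 ± 0.29 SE on the log2 scale), BIVM (-6.64 ± 0.26), the growth factor receptor FGFR2 (-6.33 ± 0.32), LYPLAL1 (-6.14 ± 0.31), THNSL1 (-6.13 ± 0.17), JRKL (-5.78 ± 0.21), HPDL (-5.66 ± 0.25) and the ubiquitin ligase SH3RF3 (-5.63 ± 0.25) made up the rest of the 10 largest falls. TAMM41, BIVM and FGFR2 fell by more than CLDN2 (-6.26). All 20 of these genes kept direction and call in the settings that tested them. DESeq2 gave a larger SE for falls to few counts as well, 0.744 for TAMM41 and 0.611 for BIVM.

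Transcripts of the pump that bufadienolides bind went both ways. ATP1B3, a beta subunit, went from 216.1 ± 4.04 to 461.0 ± 11.8 CPM (SD, n = 3), 2.13-fold, and ATP1B1, another beta subunit, fell 1.11-fold from 183.5 CPM (edgeR adjusted p = 0.0032). Of the 7 tested pump subunits 3 rose and 3 fell, with a camera adjusted p of 0.557. Members named after their values were seen are ATP1A4, with 0 counts in every DMSO library and 1.35 CPM with CS-6, and FXYD5, which fell by 1.37 on the log2 scale. Among ion transport and osmotic response genes 13 of 24 rose and 8 fell (camera adjusted p = 0.265), and NFAT5, the transcription factor of the osmotic response, rose 4.2-fold.

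Among the other panel genes, MYC fell 6.81-fold, from 145.5 ± 9.07 to 21.4 ± 0.93 CPM (SD, n = 3), and CCND1, encoding cyclin D1, fell 1.24-fold. The growth factor VEGFA rose 3.92-fold, the transcription factors STAT3 and HIF1A rose 3.68-fold and 4.03-fold, and the survival genes MCL1 and BIRC5 rose 2.41-fold and 2.39-fold. CDKN1A, the cell cycle inhibitor p21, rose 2.16-fold. FOS (chromosome 14, 75278774 to 75282230, plus strand) rose 12.1-fold, EGR1 3.25-fold and ATF3 25.3-fold. HSP90B1 fell 1.13-fold. EGFR was the only measured named gene that did not pass, with a log2 fold change of -0.04 ± 0.04 SE (edgeR adjusted p = 0.334), and its sign depends on the scaling (0.01 with DESeq2 size factors, -0.42 with total counts, where it passed the test as lower). PTGS2 was too low to test, at 0.036 CPM with DMSO and 0.024 with CS-6. The other 128 named genes all changed, with edgeR adjusted p of at most 0.0032.

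**Figure D2:**
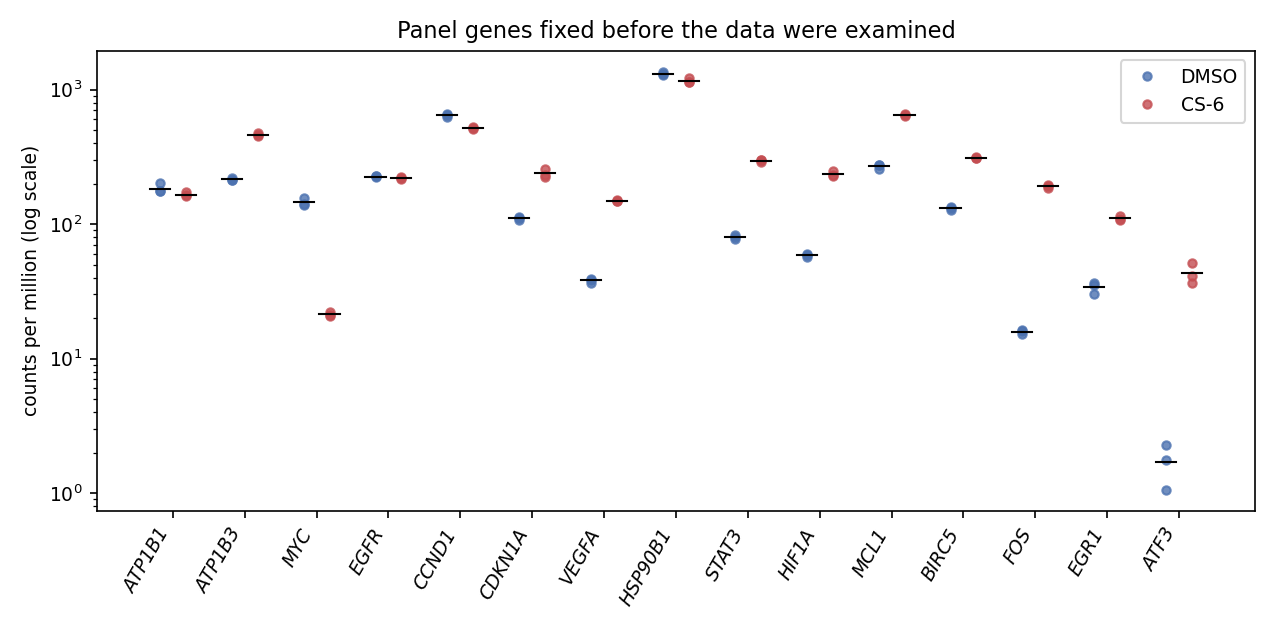
CPM on a log axis of 15 tested panel genes in the 3 DMSO (blue) and 3 CS-6 (red) libraries, with 1 point per library and a line at the group mean. MYC fell from 145.5 to 21.4 CPM and FOS rose to 190.7 CPM, while EGFR, whose sign depends on the scaling, was at 225.6 CPM with DMSO.

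Gene lists fixed before the data were examined were tested with camera at a preset correlation. It called 10 of 42 lists, 6 higher and 4 lower. Other splits of the libraries into 3 and 3, which mix the groups and gave 0 changed genes, still gave 6 to 9 called lists. The number of called lists therefore does little to separate the real grouping from mixed ones. With camera's estimated correlation 0 lists were called and 4 had an unadjusted p under 0.05. The medians of the called lists kept their sign under each scaling tried. The medians of 13 other lists changed sign with the scaling, namely pump subunits, ATF4 targets, endoplasmic reticulum chaperones, G1/S genes, pro-apoptotic genes, hypoxia genes, respiratory chain genes, epithelial adhesion genes, angiogenic factors, MYC targets, aminoacyl-tRNA synthetases, proteasome subunits and integrins. With total counts only, higher and lower members numbered 7 and 18 for proteasome subunits, 9 and 28 for respiratory chain genes, 11 and 24 for MYC targets and 12 and 13 for epithelial adhesion genes. They numbered 7 and 16 for pro-apoptotic genes, 6 and 13 for endoplasmic reticulum chaperones, 14 and 23 for hypoxia genes and 5 and 11 for aminoacyl-tRNA synthetases. The median of the p53 targets kept its sign, but with total counts only 9 were higher and 9 lower. Named genes kept their direction under each scaling, except EGFR. Adjusted over the list alone, the counts of members that rose or fell were those given here, except for 1 more fallen gene among hypoxia and glycolysis genes (18) and among nuclear-encoded respiratory chain genes (16). Where 5 or fewer members of a list went one way or did not pass, those named beyond the fixed rule were chosen after their values were seen.

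**Figure D3:**
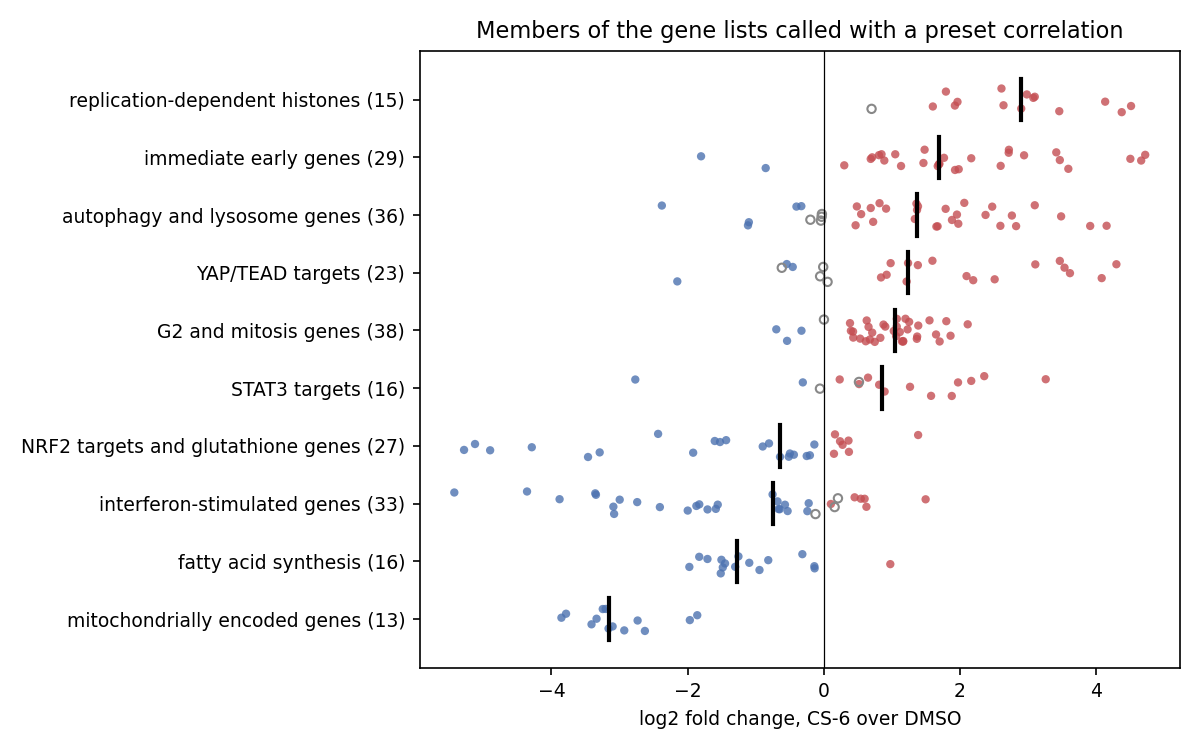
Log2 fold change (x axis) of each tested member of the 10 called lists, red where it rose, blue where it fell and open grey where it did not pass, with a black line at the list's median and the number tested in brackets. Medians run from -3.16 for the mitochondrially encoded genes to 2.90 for the replication-dependent histones.

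Immediate early genes, transcribed within minutes of a stimulus in resting cells, were higher after 24 h. Of 29 tested members 27 rose, with a median log2 fold change of 1.70 (camera adjusted p = 2.33e-06; adjusted p = 0.37 with an estimated correlation). MAFF rose 26.4-fold, FOS 12.1-fold, CYR61 (CCN1) 11.1-fold and FOSL1 6.58-fold, and DUSP2 and KLF2 fell. The YAP/TEAD targets, read-outs of the Hippo pathway, overlap this list in CYR61. Of 23 members 16 rose, 3 fell (NT5E, FJX1 and DOCK5) and 4 did not pass, with a median of 1.24 (adjusted p = 0.0029; adjusted p = 0.348 with an estimated correlation). The kinase gene LATS2 (chromosome 13, 20973032 to 21061547, minus strand) went from 52.6 ± 3.80 to 890.5 ± 51.9 CPM (SD, n = 3), 16.9-fold, CTGF (CCN2) rose 12.3-fold and AMOTL2, a binding partner of YAP, 8.62-fold. LATS2 and AMOTL2 encode inhibitors of YAP as well as being its targets.

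Autophagy and lysosome genes rose as a group, with 27 of 36 members higher, 5 lower and a median of 1.37 (camera adjusted p = 0.00016; adjusted p = 0.348 with an estimated correlation). MAP1LC3B, the LC3B protein of autophagosomes, rose 17.8-fold from 34.7 ± 1.05 to 618.2 ± 23.3 CPM (SD, n = 3). The folliculin gene FLCN rose 15.1-fold, the sialidase NEU1 11.2-fold and the proton pump subunit ATP6V0D1 6.79-fold. The 5 that fell were CTSL, MITF, WIPI1, ATG7 and CTSB. The broader GO term lysosome leaned lower, with 90 of 154 genes down and a median of -0.47 (Fisher's exact test, adjusted p = 0.0476), though not in every setting. Among all tested genes with a component term 45.43% were lower. The rise is thus shown for the listed members only, and this term does not settle how lysosomal genes at large moved. Among 26 ATF4 stress targets 12 rose and 10 fell (adjusted p = 0.355), and ATF4 itself rose 5.35-fold to 1974 CPM and the asparagine synthetase gene ASNS 7.89-fold. Endoplasmic reticulum chaperones went both ways, with 9 of 20 higher and 8 lower (adjusted p = 0.88). HERPUD1 rose 3.16-fold and PDIA4 fell 5.71-fold. The median of the chaperones was 0.02 and their mean -0.06. Of 18 heat shock chaperones 13 fell and 5 rose (CHORDC1, STIP1, DNAJA1, BAG3 and HSPA4; adjusted p = 0.23). HSPA8, the constitutive HSC70 (chromosome 11, 123057489 to 123063230, minus strand), fell 9.22-fold from 3533 ± 34.5 to 383.4 ± 16.6 CPM (SD, n = 3), and HSPA4 rose 3.14-fold. Of 31 proteasome subunits 16 rose and 9 fell (adjusted p = 0.265), with PSMD8 2.45-fold and PSMC6 2.18-fold higher.

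Genes of mitosis rose, while genes of DNA replication went both ways. Of 38 G2 and mitosis genes 34 rose and 3 fell (CDC25B, CCNA2 and KIF20A), with a median of 1.05 (camera adjusted p = 2.33e-06; adjusted p = 0.37 with an estimated correlation). CKS2 rose 4.33-fold, and NUSAP1, DLGAP5 and ANLN, which act on the spindle and in cytokinesis, rose 3.48-fold, 3.25-fold and 3.14-fold. G1/S and DNA replication genes had 15 of 45 members higher and 22 lower, with a median of -0.04 (adjusted p = 0.643). These counts depend on the scaling, with 8 higher and 35 lower with total counts only and 9 and 31 with upper-quartile factors. The helicase subunit MCM4 fell 3.03-fold. Replication-dependent histone transcripts, which lack a poly(A) tail in cycling cells, were low and rose in 14 of 15 members, with a median of 2.90 (adjusted p = 0.00075; adjusted p = 0.348 with an estimated correlation). HIST1H2BD (H2BC5) went from 1.87 ± 0.23 to 38.9 ± 2.94 CPM (SD, n = 3), and HIST1H2BJ (H2BC11), HIST1H1C (H1-2) and HIST1H2AC (H2AC6) rose 22.8-fold, 7.46-fold and 6.23-fold. HIST1H2AL did not pass (0.70 ± 0.38 SE on the log2 scale). Near-identical copies within histone clusters can share reads, so values for single histone genes are uncertain.

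Homologous recombination and Fanconi genes had 21 of 35 members lower and 12 higher (camera adjusted p = 0.265). FANCF fell 48.8-fold from 17.9 CPM and NBN, a subunit of the complex that senses double-strand breaks, 12.3-fold. Of 25 p53 targets 18 rose and 7 fell (adjusted p = 0.0937). The death receptor gene TNFRSF10B rose 3.5-fold to 610.2 CPM and the nuclease gene AEN 3.36-fold. Pro-apoptotic genes had 12 of 27 higher and 11 lower (adjusted p = 0.907), or 9 and 15 with upper-quartile factors. TNFRSF10B rose and the TNF receptor gene TNFRSF1A fell 3.04-fold. Their median was -0.01 and their mean -0.19, while camera ranked them higher. Anti-apoptotic genes had 13 of 19 members higher and 6 lower (adjusted p = 0.125), and those with the smallest p were BIRC6, a ubiquitin-conjugating inhibitor of apoptosis (3.01-fold higher), and MCL1, which rose.

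All 13 mitochondrially encoded mRNAs fell, by a median of 3.16 on the log2 scale (camera adjusted p = 4.25e-05; adjusted p = 0.429 with an estimated correlation). MT-CO1, a subunit of cytochrome c oxidase (mitochondrial genome, 5904 to 7445, plus strand), fell 8.58-fold from 17780 ± 869 to 2073 ± 95.2 CPM (SD, n = 3). MT-CO2 fell 10.6-fold, MT-CO3 9.21-fold and the complex I subunit MT-ND4 10.1-fold. Together these 13 mRNAs made up 5.69% ± 0.16 of counts with DMSO and 0.582% ± 0.029 with CS-6 (SD, n = 3). The nuclear-encoded respiratory chain genes had 24 of 45 members higher and 15 lower (adjusted p = 0.593). NDUFB10, of complex I, fell 5.95-fold. The list's median was 0.19 and its mean -0.03.

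**Figure D4:**
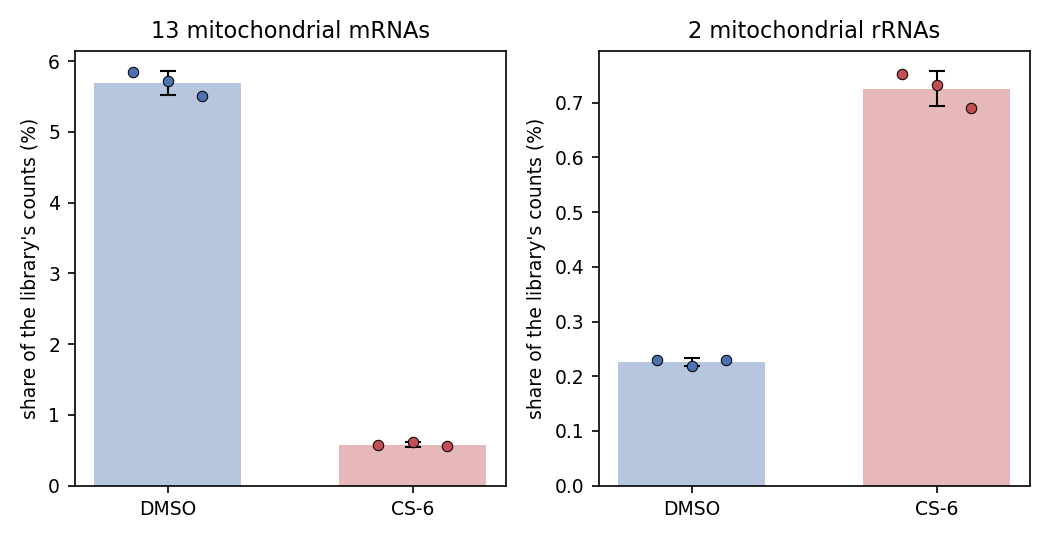
Share of each library's counts (y axis, %) from the 13 mitochondrial mRNAs (left) and the 2 mitochondrial rRNAs (right), with bars at the group mean, error bars of 1 SD and 1 point for each of the 3 libraries. The mRNA share was 5.69% with DMSO and 0.582% with CS-6, and the rRNA share 0.226% and 0.725%.

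Fatty acid synthesis genes fell in 15 of 16 members, with a median of -1.28 (camera adjusted p = 0.0033; adjusted p = 0.37 with an estimated correlation). SCD, the stearoyl-CoA desaturase, fell 3.55-fold from 477.9 ± 20.5 to 134.5 ± 3.10 CPM (SD, n = 3), ACLY, the ATP-citrate lyase, 2.85-fold and FASN, the fatty acid synthase, 2.13-fold. ACSL3 rose 1.97-fold. ELOVL5, a further member that most cells express, is listed at 0 in all 6 libraries, so a 0 in these counts may not mean absence. Cholesterol synthesis and uptake genes had 13 of 24 members lower and 7 higher (adjusted p = 0.367), and the 2 with the smallest p both rose, the regulator SREBF2 4.86-fold and the synthase HMGCS1 3.31-fold. Hypoxia and glycolysis genes had 19 of 39 members higher and 17 lower (adjusted p = 0.88). The glucose transporter SLC2A3 rose 13.6-fold to 360.5 CPM, and GPI, a glycolytic isomerase, fell 4.06-fold. Their median was -0.01 and their mean 0.10.

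Of 27 NRF2 targets and glutathione genes 20 fell and 7 rose, with a median of -0.64 (camera adjusted p = 0.0213; adjusted p = 0.37 with an estimated correlation). The aldo-keto reductase gene AKR1B10 went from 137.7 ± 7.78 to 3.53 ± 0.17 CPM (SD, n = 3), 38.9-fold lower, AKR1C1 fell 11-fold and the quinone reductase NQO1 3.78-fold. AKR1C genes are near-identical and can share reads. Metallothioneins had 4 tested members, too few for camera. MT1E fell 23.6-fold and MT2A 4.77-fold. MT1F fell by 4.37 on the log2 scale, and the zinc exporter SLC30A1 rose by 0.78.

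Interferon-stimulated genes fell in 24 of 33 members and rose in 6, with a median of -0.75 (camera adjusted p = 0.0213; adjusted p = 0.37 with an estimated correlation). OAS3, a sensor of double-stranded RNA, fell 8.45-fold from 158.9 ± 5.88 to 18.8 ± 0.52 CPM (SD, n = 3), OAS1 43.0-fold, SAMD9 20.5-fold and PARP9 6.68-fold. STAT3 targets rose in 12 of 16 members, with a median of 0.85 (adjusted p = 0.0119; adjusted p = 0.366 with an estimated correlation). STAT3 itself, JUNB (4.49-fold) and VEGFA rose, and MYC, a promoter of growth, and CCND1 fell. NF-kB targets and cytokines were split, 10 of 21 higher and 11 lower (adjusted p = 0.957), with ICAM1 2.33-fold and NFKB1 2.15-fold higher.

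EGFR ligands and ERK feedback genes rose in 15 of 25 members and fell in 9 (camera adjusted p = 0.181). The receptor gene EPHA2 rose 4.51-fold to 1631 CPM and FOSL1 6.58-fold. Of 15 glucocorticoid receptor targets 11 rose and 4 fell (MT2A, CRISPLD2, NFKBIA and FKBP5; adjusted p = 0.0545), with the clock gene PER1 17-fold and GADD45B 11.6-fold higher. TGF-beta targets had 15 of 25 members higher and 9 lower (adjusted p = 0.318), CTGF rising and the transcriptional inhibitor ID1 falling 11.8-fold. Wnt/beta-catenin targets had 14 of 20 lower and 4 higher (TCF7, LGR5, ZNRF3 and TCF7L2; adjusted p = 0.0696), MYC and the Wnt inhibitor RNF43 (5.17-fold) falling. Notch targets had 8 of 15 lower and 5 higher (HES1, NOTCH2, JAG2, MAML2 and NOTCH3; adjusted p = 0.355), the ligand gene JAG1 falling 3.72-fold and HES2 24.5-fold. Angiogenic factors had 10 of 19 higher and 8 lower (adjusted p = 0.792), with VEGFA higher and SEMA3B 5.52-fold lower. Their median was 0.36 and their mean -0.12.

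MYC targets and ribosome biogenesis genes had 18 of 38 members higher and 16 lower (camera adjusted p = 0.957), or 11 and 23 with upper-quartile factors. PAICS, of purine synthesis, fell 4.77-fold and MYBBP1A 4.55-fold, and the list's median was 0.06 and its mean -0.20. Cytosolic ribosomal proteins had 40 of 66 lower and 18 higher (adjusted p = 0.0719), with RPS24 3.6-fold lower. With total counts only 56 were lower and 9 higher. Ribosomal protein genes have many processed pseudogenes that can share reads. Aminoacyl-tRNA synthetases had 10 of 20 higher and 9 lower (adjusted p = 0.87), YARS (YARS1) rising 3.22-fold and QARS (QARS1) falling 5.82-fold, with a median of 0.06 and a mean of -0.11.

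Lists of breast lineage and adhesion did not pass. Luminal breast epithelial markers had 14 of 18 members lower and 3 higher (camera adjusted p = 0.0519). CA12, a carbonic anhydrase, fell 11.2-fold, and AREG, a ligand of EGFR, rose 15.7-fold along with FOXA1 and SPDEF. Basal breast epithelial markers had 9 of 13 lower and 3 higher (adjusted p = 0.139), the laminin gene LAMB3 rising 3.70-fold with SFN and S100A2, and the integrin gene ITGB4 falling 2.48-fold. Breast cancer stem cell genes had 12 of 18 lower and 5 higher (EZH2, LGR5, TSPAN8, BMI1 and KLF4; adjusted p = 0.125), ID1 and MYC having the smallest p. Epithelial adhesion and junction genes had 17 of 27 higher and 8 lower (adjusted p = 0.161), or 13 and 11 with upper-quartile factors, the tight junction gene OCLN rising 3.72-fold and the desmosome gene PKP3 falling 6.59-fold. Mesenchymal transition genes had 10 of 20 lower and 8 higher (adjusted p = 0.957), with ITGA5 2.68-fold and ZEB1, a repressor of epithelial genes, 4.58-fold higher. Integrins and extracellular matrix genes had 16 of 32 higher and 15 lower (adjusted p = 0.761), with LAMB3 higher and the syndecan gene SDC1 5.46-fold lower, and their median was 0.18 and their mean -0.34.

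Markers of other cell types moved both ways. Endothelial markers rose in 4 of 6 members (camera adjusted p = 0.367), MMRN2 from 3.64 ± 0.18 to 30 ± 4.45 CPM and ESAM from 11 ± 1.25 to 26.8 ± 3.65 (SD, n = 3), with CLDN5 and ERG also higher and PECAM1 lower (EGFL7, at -0.18 on the log2 scale, did not pass). Leukocyte markers rose in 5 of 8 (adjusted p = 0.367), CD14 from 0.249 ± 0.130 to 13.6 ± 1.43 CPM and CSF1R from 0.232 ± 0.108 to 5.28 ± 1.09 (SD, n = 3), with ITGAM, CD79A and SPI1 higher, CD8A and CORO1A lower, and CD4 not passing. The leukocyte marker with the most counts had a mean of 6.90 CPM over all libraries, and PTPRC, the pan-leukocyte marker, is listed at 0 throughout. As for ELOVL5, such a 0 may not mean absence. Of 26 basal breast epithelial markers, which stand for the line itself, 21 had a count, and KRT6A, KRT6B, TP63, SOX10 and VGLL1 had none. Of 3 tested fibroblast markers, too few for camera, PDGFRB fell 6.75-fold from 3.29 CPM and COL1A1 1.85-fold from 3.25 CPM, and FBN1 did not pass (-0.21 on the log2 scale).

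The authors' deposited table gives 14321 genes an adjusted p under 0.05. Of these, 12785 were tested here and 12780 were called here too, all in the same direction. With a change of at least 2-fold in both, 8082 genes were shared, again all in one direction. The table marks 4556 genes as significant, 1798 higher and 2758 lower, and all 3857 of them that were tested here were called in the same direction. Both start from the same counts, so this overlap is no independent evidence.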

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

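The number of changed genes stayed within 1.5 times of 13711 under each alternative, from 12555 with limma on log2(FPKM + 0.1) to 16233 with no low-count filter, and of the genes called under both, those called with DESeq2 size factors (13532), no filter (13456) and the DESeq2 Wald test (12810) all kept their direction. With upper-quartile factors 12495 of 12758 shared genes kept it, with total counts only 12288 of 12682, and with limma on log2(FPKM + 1) 10619 of 10977. Genes at least 2-fold higher numbered 1736 with limma on log2(FPKM + 1) and 2333 with log2(FPKM + 0.1), against 3661. FPKM is scaled by library totals, and edgeR with total counts only gave 2559 such genes. Scaling alone thus lowered the number. The limma runs differ only in the pseudocount, so the larger pseudocount lowered it from 2333 to 1736. What else parts limma with the smaller pseudocount from edgeR with total counts only was not tested. Called lists numbered 18 with no low-count filter, where more genes were compared, 0 with an estimated correlation and 41 with fry, which does not compare a list with other genes. The direction was reversed with fry for mesenchymal transition genes (adjusted p = 0.0111), angiogenic factors (0.000495), MYC targets and ribosome biogenesis (7.65e-06) and aminoacyl-tRNA synthetases (0.00894), and the cause was not tested. The overlap with the authors' table was 8082 genes at least 2-fold changed in both, against 12780, a stricter demand by construction. Annotation terms numbered 24 with genes changed at least 2-fold, against 72, an alternative chosen after seeing the data, as were the other scalings for terms (79, 64 and 64) and limma on log2 CPM (13585, or 13559 after removing trends on GC content and length). Without each library in turn, changed genes numbered 13747 to 13857, higher genes 6524 to 6582, lower genes 7223 to 7285, genes at least 2-fold higher 3762 to 3873, genes at least 2-fold lower 4809 to 4911 and called lists 10 to 13. Depth limits genes near the floor of 3 counts.

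The replicate numbers do not pair the libraries, since deviations of libraries with the same number correlated across genes at 0.0201, -0.00514 and 0.0142. With a replicate block 13661 genes changed, and the 13638 shared with the fit without it all kept their direction.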

Other observations

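The gene lists of this part were chosen after the data were seen. So were the tests by scaling, by non-polyadenylated RNA and by S phase, and the comparison of other splits for changed genes. Camera's p-values for the lists of this part were adjusted over these lists alone, not over the 42 fixed lists. As the lists were picked from the same data, their p-values are descriptive only. Clock genes rose in 14 of 17 members, with a median log2 fold change of 2.25 (camera adjusted p = 0.000351; adjusted p = 0.103 with an estimated correlation). NR1D1, a repressor of the clock, went from 24.6 ± 0.64 to 866.9 ± 9.93 CPM (SD, n = 3), and PER2 rose by 3.47 and NR1D2 by 2.88 on the log2 scale, while HLF and CLOCK fell. Targets of MondoA and ChREBP, sensors of glucose metabolites, rose in 7 of 8 members (median 1.72, adjusted p = 0.00669; adjusted p = 0.103 with an estimated correlation), with TXNIP at 4.62 and ARRDC4 at 4.38, and MXD4 fell. Nonsense-mediated decay factors rose in 11 of 14 (median 1.0, adjusted p = 0.00624; adjusted p = 0.103 with an estimated correlation), led by UPF2 (2.27) and SMG1 (2.16), with SMG8, SMG9 and RBM8A lower. Splicing regulators whose transcripts carry poison exons rose in 22 of 28 (median 0.47, and 0.09 with total counts only, adjusted p = 0.0041; adjusted p = 0.125 with an estimated correlation), with the kinases CLK1 at 2.52 and CLK4 at 2.31 and SRSF1, SRSF2, SRSF4, TIA1 and LUC7L lower.

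By Fisher's exact test, 31 of 1610 biological process terms and 35 of 380 cellular component terms were enriched among higher genes. The test treats genes as independent and allows for no correlation between members of a term, so its p-values can be too small. Of all tested genes with a process term 43.22% were higher. For genes with a component term 42.72% were higher and 45.43% lower. Among lower genes 0 process terms (106 at an unadjusted p under 0.05) and 6 component terms were. Nuclear speck (118 of 164 genes higher, adjusted p = 9.143e-12), nucleosome (33 of 39, adjusted p = 1.564e-05), mRNA processing (115 of 181, adjusted p = 1.178e-05) and cytoplasmic stress granule (27 of 39, adjusted p = 0.0171) held with every scaling and with genes changed at least 2-fold. Among lower genes peroxisome held in each of these settings (54 of 83, median -0.83, adjusted p = 0.0226). Mitochondrial matrix (154 of 253 lower, adjusted p = 0.000173) was lost with genes changed at least 2-fold (adjusted p = 0.0843). Lysosome was among the lower terms (90 of 154, adjusted p = 0.0476), whereas 27 of 36 genes of the fixed autophagy and lysosome list rose, and it was lost with DESeq2 size factors (adjusted p = 0.0543), total counts (adjusted p = 0.0785) and genes changed at least 2-fold (adjusted p = 0.534). Of 678 tested lincRNAs 372 fell and 193 rose (median -0.81). Single-exon protein-coding genes had a median of -0.545 and those with over 20 exons 0.10, or -0.244 and 0.269 after removing trends on GC content and length (limma).

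Most tested genes changed. Of the 10 splits of the libraries into 3 and 3, only 1, the real one, gave as many changed genes (13711 with edgeR, highest other 0), with 3 to 9 genes at an unadjusted p under 0.05 in the others (edgeR). DESeq2 called 14381 genes in the real split and 0 in each other split after adjustment. The real split gave 8328 genes changed at least 2-fold (highest other 0, edgeR) and 10 called lists (6 to 9 in the other splits). Each other split mixes both groups unevenly, so it still carries part of the difference between them. With 10 splits a share under 0.05 cannot be reached. The lowest count over the other scalings was 13710, but a scaling moves all genes of a library alike, so this count could hardly drop. What argues against scaling as the whole cause is that changes went both ways. With TMM factors 3661 genes were at least 2-fold higher and 4667 at least 2-fold lower, and 1 shift cannot make both. The values argue against GC content and length bias, since 8216 genes changed at least 2-fold after its removal and 8187 before (limma). A response to CS-6, the difference between the groups that the labels give, remains as a hypothesis.

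The mitochondrial mRNAs fell while MT-RNR1 and MT-RNR2, the mitochondrial rRNAs, rose by 2.48 and 1.97 on the log2 scale. Scaling cannot part them, and the median of the mRNAs minus the mean of the rRNAs was -5.388 (-5.452 to -5.286 without each library in turn). More non-polyadenylated RNA in the CS-6 libraries could raise the rRNAs and stays open. Only 6 such RNAs were tested, mostly with few counts (median of their mean CPM 1.33). They went both ways (median log2 fold change 0.507, interval -1.02 to 2.12), so they cannot decide. Lower nuclear-encoded mitochondrial gene expression factors stay open as well, with 11 of 25 higher and 11 lower (median 0.0144, interval -0.534 to 0.517), TFAM at 1.49 and TFB1M at -3.50.

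The histone transcripts rose by a median of 2.90. More cells in S phase would raise replication genes. Their median of -0.0428 (interval -0.353 to 0.140) lay below the bound of 0.415, set above the median of all tested genes (-0.0846). It also lay below 1.96, where the interval of the histones began. How far replication genes move for a given rise of histones was not measured, so that comparison cannot decide. The replication genes thus showed no rise as a group, and S phase as a cause of the histone rise is not settled. Across scalings the replication median ran from 0.0013 (DESeq2 size factors) to -0.42 (total counts only). The histone median stayed at 2.52 or above. More non-polyadenylated RNA, which could raise transcripts without a poly(A) tail, cannot be told apart from a change in the histones. The medians differed by 2.39, but the interval of the non-polyadenylated RNAs reached 2.12 and that of the histones began at 1.96. Most of these RNAs also had few counts. A hypothesis that reduced nonsense-mediated decay raised its known target transcripts was tested on small nucleolar RNA host transcripts, of which 9 of 19 rose and 7 fell. Their median of 0.0149 (interval -0.473 to 0.393) lay below the bound of 0.415, but a median over members that went both ways does not decide, so the hypothesis stays open.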
